A study of Mus musculus with 6 samples.

How the data were processed

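Double negative thymocytes sorted by flow cytometry were profiled on 6 single-colour arrays, 3 labelled wild type and 3 labelled Egr1/Egr3 double knockout, with 1 animal for each array per the labels. The sorting is taken from the sample descriptions. Titles and source names speak of whole thymus, and how the 2 fit together is not given in the sources used here. The deposited values are linear intensities, 1 for each probe set and array. Their mean over the middle 96% of values is 150 on each of the 6 arrays in the deposited table, so each array was scaled to a common trimmed mean. The scanner software, the summary of probes into probe sets, the mouse strain and the sex of the animals are not given in the sources used here, and neither scanner files nor detection calls were used. The arrays carry RNA described per the labels as amplified.

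Groups and replicate numbers were taken from the sample labels. The table holds 45101 probe sets. After 64 control probe sets were left out, 45037 remained. Genes were named through a platform annotation table, in which 34945 of these probe sets have 1 gene symbol, 932 have several and 9160 have none here. Symbols were updated through a RefSeq gene table of the mouse assembly GRCm38.p6, in which 34742 of the 34945 matched and the others kept the annotation's symbol. That table was used for names and for the order of genes along chromosomes.

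An offset of 16 was added and log2 taken, so a log2 change is on the scale of intensity plus 16 and understates changes of dim genes. The medians of the arrays differed by 0.126 on this scale, above a limit of 0.1 fixed before the data were examined, so each array was centred on its median. Probe sets with a mean log2 value under the 40th percentile (4.87, an intensity of 13.2) were left out of the test, which left 27022. A change is the mean of the arrays labelled double knockout minus the mean of the arrays labelled wild type. It was tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with p-values adjusted by the Benjamini-Hochberg method at a threshold of 0.05. SE is the moderated standard error of that fit. At gene level, a gene with exactly 1 symbol was represented by its probe set of highest mean, which gave 13187 genes, and the adjustment was repeated over them. Egr1 and Egr3 values come from the fit without the intensity filter.

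The 29 gene lists were fixed before the data were examined. Of their 616 genes, 570 were named on the array and 536 tested. The 28 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, which compares the mean test statistic of a list's genes with that of other genes. Beside it stand camera with a correlation estimated from the data and fry, which asks whether the genes of a list move, on balance, one way. Of the 12 lists that passed camera, 1 held with an estimated correlation. The size of the correlation does not by itself account for all of these losses. A call lost with an estimated correlation is therefore not by itself a sign of correlated genes. For the Notch list it was estimated at 0.00018, under the preset, yet camera's unadjusted p went from 0.000556 to 0.0212. For the ribosome biogenesis list it was 0.011, near the preset, and p went from 2.86e-16 to 0.00124. The adjusted p of 0.106 shared by several lists came from unadjusted camera values between 0.0126 and 0.0302. Fry passed 10 lists. Its mixed test, for change in either direction, passed 23. Adjusted over the list alone means that the Benjamini-Hochberg adjustment was made over the genes of that list. Genes in the neighbourhood of Egr1 and Egr3 were compared with all others by Fisher's exact test.

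The rule for named genes was also fixed before the data were examined. It takes Egr1 and Egr3, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold and without overlap between the groups, and up to 4 genes of smallest p in each list. A gene known only by a clone identifier gave way to the next gene. Genes named by another route are marked as such.

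The alternatives tried were values as deposited, quantile normalization, offsets of 1 and 64, no filter and a filter at the 60th percentile, no intensity trend, array weights, the replicate number as a block, each array left out in turn, other rules for the probe set of a gene, other list tests and windows of 50 and 200 genes. A fit with a granulocyte score as a covariate was added after seeing the data. The gene test was tested on simulated data with the means and spreads of the 13187 genes. With 200 genes changed by 1 on the log2 scale it recovered 22.5% of them, with 4 false calls, and with changes of 2 it recovered 98.5%, with 15 false calls. With no gene changed it made 0 calls. With the ribosome biogenesis list lowered by 1, camera called that list and 0 others. The simulated genes were drawn independently, whereas estimated correlations within lists of the real data reached 0.54 (erythroid genes). The simulation thus could not show false list calls that come from correlated genes. Figures were drawn with matplotlib 3.10.9.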

Results

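Gene expression was measured in double negative thymocytes, the early T cell precursors of the thymus that carry neither the CD4 nor the CD8 coreceptor. The cells are described as sorted by flow cytometry, per the labels from 3 wild type mice and from 3 double knockouts of Egr1 and Egr3. These 2 genes encode zinc finger transcription factors that are induced by signals of the pre-T cell receptor. The sample titles and source names speak of whole thymus, the descriptions of sorted cells. The descriptions are followed here, and values of cell type genes hold for sorted cells only if they are right. Per the labels, each animal gave 1 single-colour array with 45101 probe sets, of which 64 are controls. Sex-linked signals described at the end leave open whether wild type replicate 1 and the arrays labelled double knockout each hold RNA of 1 animal only. The deposited intensities had medians between 19.9 and 23.1 on the 6 arrays. On each array the brightest of 27 control probe sets for genes of the bacterium Bacillus subtilis read between 19.0 and 29.9. This gives an upper level for probe sets without a target, as the median of the 27 lay between 2.95 and 5.47. Both Cd4 probe sets lay under the brightest control on the 6 arrays, between 3.03 and 10.1, as cells sorted to lack CD4 would. A single gene at this level does not settle the source of the RNA. The CD8 genes Cd8a and Cd8b1 passed the intensity filter, which Cd4 did not, so the low level is shown for CD4 only. With 3 arrays in each group, their number limits the precision of every value. The comparison asks which transcripts differ between thymocytes of the 2 genotypes at this stage.

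The targeted genes were examined first. The single Egr1 probe set read 508, 509 and 455 on the 3 arrays labelled wild type and 1757, 1696 and 1221 on the 3 arrays labelled double knockout. Egr1 was thus higher, not lower, in the arrays labelled double knockout, by 1.60 on the log2 scale (SE 0.22, n = 3 and 3, adjusted p = 0.00371). Without double knockout replicate 1 the change of 1.49 had an adjusted p of 0.0613. Egr3 was dim on all arrays. Its brighter probe set read 92.2, 83.1 and 30.8 on the wild type arrays and 34.4, 45.8 and 32.9 on the arrays labelled double knockout, a log2 change of -0.59 (SE 0.35, adjusted p = 0.528). Its other probe set gave -0.07 (SE 0.36, adjusted p = 0.964). The place of these probe sets relative to the disrupted part of each gene is not given in the sources used here, and a probe set outside that part checks nothing. Because the Egr1 signal neither bears out nor refutes the labels, every direction below is stated for the arrays labelled double knockout relative to the arrays labelled wild type. In the EGR and NAB family list, Egr1 was the only member of 5 tested to change, also when adjusted over the list alone. Egr2 had a log2 change of 0.59 (SE 0.30; 0.93, SE 0.33, on its other probe set), Egr4 of -0.41 (SE 0.35) and the corepressor Nab1 of 0.20 (SE 0.25), and none of the 3 passed the test. Dimmer probe sets of Nab1 gave 1.09 (SE 0.25, adjusted p = 0.0524) and -0.36 (SE 0.36). The list as a whole did not differ from other genes (median log2 change 0.20, camera adjusted p = 0.388, and adjusted p = 0.651 with an estimated correlation).

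**Figure D1:**
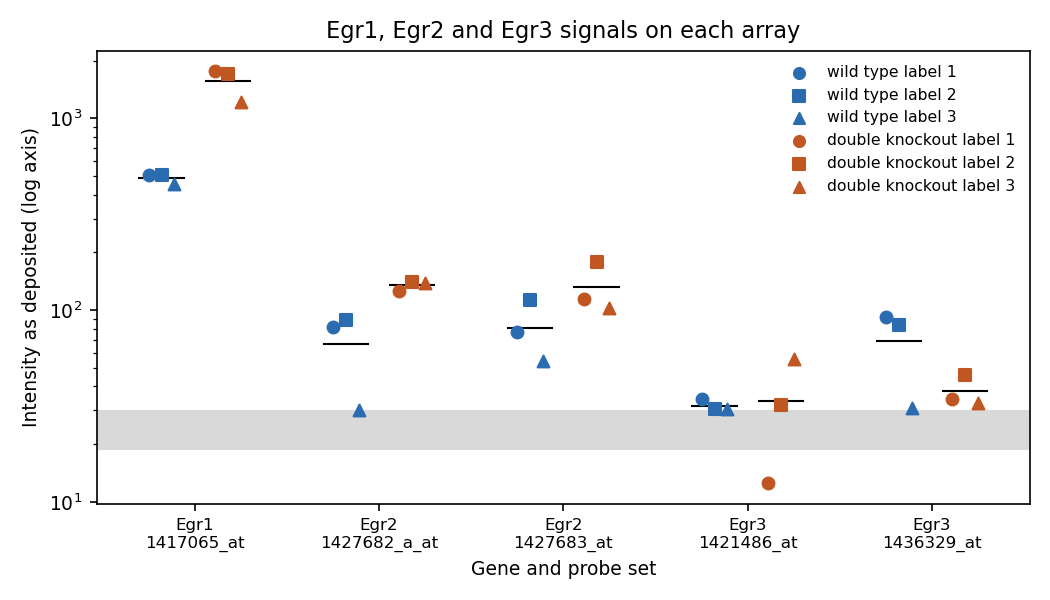
Deposited intensity (log axis) of each Egr1, Egr2 and Egr3 probe set on each of the 6 arrays, with lines at the group means and a grey band from 19.0 to 29.9 for the brightest bacterial control probe set of the arrays. Egr1 lies between 1221 and 1757 on the arrays labelled double knockout, above the 455 to 509 of the arrays labelled wild type. The Egr3 probe sets lie between 12.5 and 92.2, from below to above the grey band.

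On the scale of intensity plus 16, many of the largest rises in the arrays labelled double knockout were in genes that the wild type arrays read at or near the level of the brightest bacterial controls. Dmbt1, a scavenger receptor glycoprotein, rose by 4.76 on the log2 scale (SE 0.23, adjusted p = 3.62e-06), from 1.00 ± 0.496 to 451 ± 53.5 (mean intensity and SD, n = 3 each). Mapk13, the p38 delta kinase, rose by 4.73 (SE 0.31), and Cables1, a binding partner of cyclin-dependent kinases, rose by 4.39 (SE 0.22), which its other probe set also showed (4.22, SE 0.25). Also higher were the cysteine protease inhibitors Stfa3 (4.02, SE 0.37) and Stfa2l1 (3.79, SE 0.43), the protease cathepsin E, Ctse (3.90, SE 0.49), the zinc finger gene Plagl1 (3.83, SE 0.26), Epb41l4a (3.76, SE 0.26), Scrg1 (3.72, SE 0.31), the pyrophosphate transporter Ank (3.68, SE 0.30) and the lipoprotein receptor Lsr (3.50, SE 0.40). The Plagl1 probe set is of the kind marked as reading several sequences. Dimmer probe sets gave 0.67 (SE 0.37) and 0.01 (SE 0.13) for Plagl1 and -0.02 (SE 0.30) for Ctse, and none of them passed. Gdpd3, a phosphodiesterase, had a change of 5.90 (SE 1.29, adjusted p = 0.021), but it read 2264, 31.8 and 2.33 on the wild type arrays and between 7056 and 8428 on the others, and its call was lost when wild type replicate 2 or any 1 of the arrays labelled double knockout was left out (adjusted p up to 0.11).

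The largest falls in the arrays labelled double knockout included Srm, the spermidine synthase of polyamine production, which fell by 2.85 on the log2 scale (SE 0.22, adjusted p = 7.43e-05), from 3509 ± 458 to 476 ± 29.6 (mean intensity and SD, n = 3 each). Bex1 fell by 2.96 (SE 0.25), Rbfa, a mitochondrial ribosome assembly factor, by 3.12 (SE 0.27) and Scin, the actin-severing protein scinderin, by 3.95 (SE 0.39). Zfp277 fell by 4.02 (SE 0.28), Myzap fell by 3.27 (SE 0.29), the microtubule-associated ubiquitin ligase Mid1 fell by 3.28 (SE 0.41), Rpgrip1 by 3.12 (SE 0.46), the phosphatase Mtm1 by 2.84 (SE 0.37) and Smim5 by 2.38 (SE 0.32). Dimmer probe sets gave 0.54 (SE 0.27), 0.09 and -0.05 for Rpgrip1, and 0.53 (SE 0.39) and -0.74 (SE 0.29) for Mtm1. Those of Mid1 gave -0.68 (SE 0.30) and -0.03, and that of Zfp277 gave -0.34 (SE 0.29). None of these dimmer probe sets passed. Gja1, connexin 43, fell by 3.04 (SE 0.40) on its brightest probe set, of the kind marked as reading several sequences. Its other probe sets of that kind gave -2.24 (SE 0.44, limma adjusted p = 0.0253), -1.42 (SE 0.31, adjusted p = 0.043) and -0.90 (SE 0.31, adjusted p = 0.196) without the intensity filter. Its 2 probe sets of another kind were dim (means of 26.9 and 11.8 on the wild type arrays) and gave -0.92 (SE 0.31) and 0.44 (SE 0.30), and neither passed. Cep85 fell by 3.19 (SE 0.28) on 1 probe set, while its other bright probe set gave -0.07 (SE 0.27) and stood for the gene, with a change of 0.04, when wild type replicate 3 was left out, and of -0.27 (adjusted p = 0.668) when wild type replicate 1 was left out. In 6 of these 24 genes, all 3 arrays of the dimmer group read at or below the brightest bacterial control (Dmbt1, Mapk13, Scrg1, Zfp277, Mid1 and Myzap), so their folds on the scale of intensity plus 16 are understated.

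**Figure D2:**
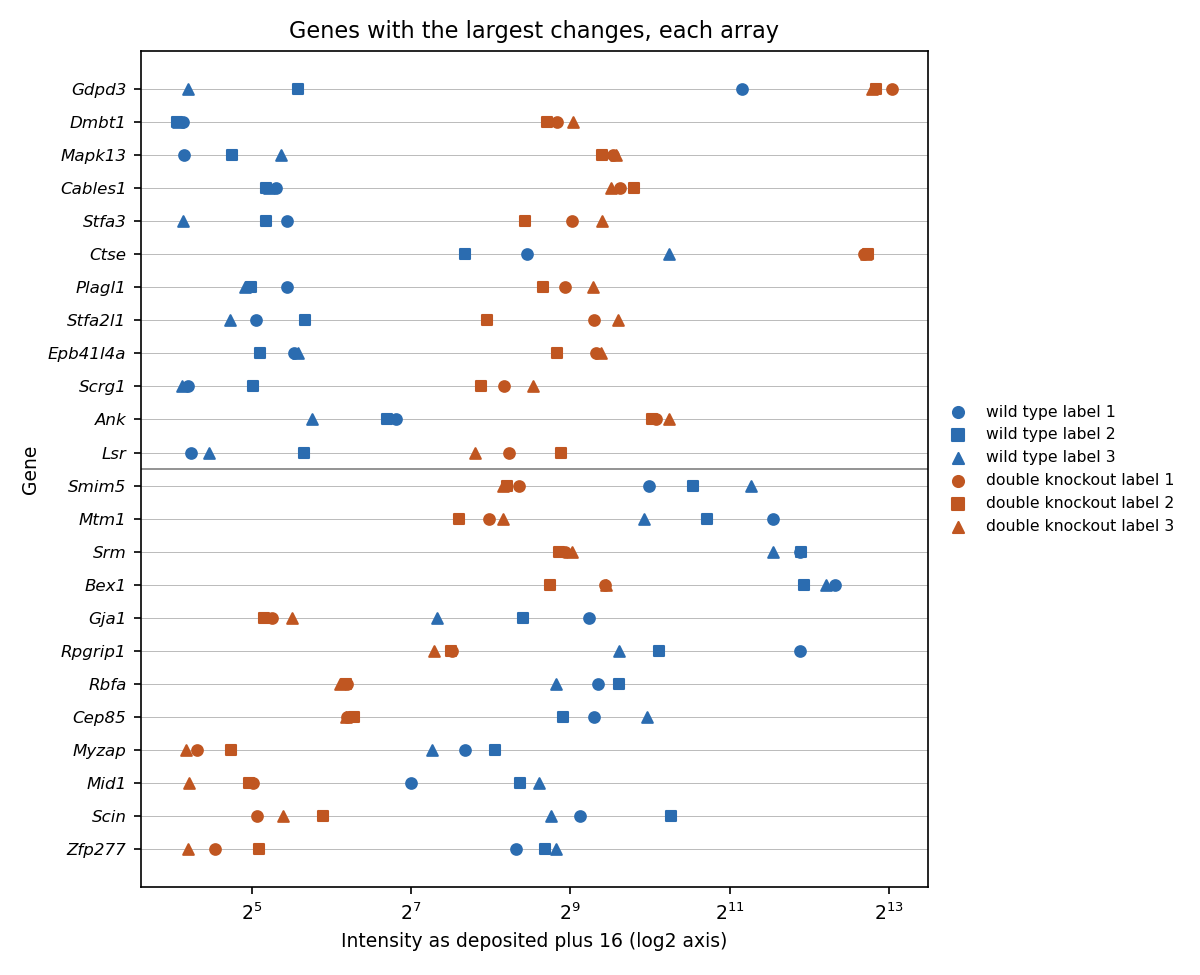
Intensity plus 16 (log2 axis) on each of the 6 arrays for the 12 genes with the largest rises on this scale (above the line) and the 12 with the largest falls (below it) in the arrays labelled double knockout. Groups do not overlap for any of the 24 genes, and Gdpd3 spreads from 2.33 to 2264 in intensity over the wild type arrays.

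Across the array, 1358 of 27022 probe sets tested changed at an adjusted p of 0.05, 787 higher and 571 lower in the arrays labelled double knockout. With 1 probe set for each gene, 920 of 13187 genes changed, 546 higher and 374 lower, and 768 of them by at least 1 on the log2 scale. An unadjusted p under 0.05 was found for 2755 genes. The groups did not overlap in 3443 genes (26.1%, where chance gives 10%). The count of changed genes moved with the arrays used: it was 518 without wild type replicate 1, 526 without wild type replicate 2, 1903 without wild type replicate 3, and 279, 474 and 479 without double knockout replicates 1, 2 and 3. With array weights it was 2909.

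Of the genes of the pre-T cell receptor stage, Ptcra, Il2ra and Dntt were lower in the arrays labelled double knockout and Il7r was higher. Ptcra, the pre-T cell receptor alpha chain, fell by 1.89 on the log2 scale (SE 0.21, adjusted p = 0.000602), from 4547 ± 526 to 1240 ± 210 (mean intensity and SD, n = 3 each). Il2ra, the CD25 marker of this stage, fell by 1.20 (SE 0.22) and Dntt, the template-independent DNA polymerase of receptor rearrangement, by 0.72 (SE 0.16), whereas Il7r, the interleukin 7 receptor chain, rose by 1.50 (SE 0.21). Of 24 genes tested in the DN3 and pre-TCR list, these 3 fell and this 1 rose (4 and 2 when adjusted over the list alone), and the list as a whole did not pass (median -0.16, camera adjusted p = 0.0819, and adjusted p = 0.471 with an estimated correlation). It passed without wild type replicate 1 (adjusted p = 0.0119). Notch target genes fell as a list, with 4 of 15 lower and none higher (5 lower when adjusted over the list alone). These were Ptcra, Il2ra, the growth regulator Myc (-1.86, SE 0.25) and Runx1 (-1.40, SE 0.33), for which another bright probe set gave -0.12 (SE 0.25), while dimmer ones gave between -1.40 and 0.13. The Notch list's median change was -0.46 (camera adjusted p = 0.00195, but adjusted p = 0.106 with an estimated correlation). Of its 15 genes, 9 are also in other lists.

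Genes of mature and emigrating T cells rose in the arrays labelled double knockout. Of 22 tested, 9 were higher and none lower (13 higher when adjusted over the list alone), with a median log2 change of 1.02 (camera adjusted p = 3.74e-09, but adjusted p = 0.106 with an estimated correlation). Gimap6, a GTPase of lymphocyte survival, rose by 2.06 (SE 0.24), the surface protein gene Ms4a4b by 1.73 (SE 0.22) and Ctla4, an inhibitory receptor, by 1.89 (SE 0.30), beside Il7r. In the NK and cytotoxic cell list, 5 of 20 genes rose and none fell, also when adjusted over the list alone. They were the granule protein gene Nkg7 (2.96, SE 0.31, adjusted p = 0.000418), the granzyme Gzmb (1.45, SE 0.22), the receptor chain Klrd1 (1.82, SE 0.32), the interleukin receptor chain Il2rb (2.02, SE 0.37) and the transcription factor Tbx21 (0.84, SE 0.22). The median of this list was 0.48 (camera adjusted p = 0.00329, but adjusted p = 0.417 with an estimated correlation). Without wild type replicate 3, the array nearly without granulocyte transcripts described below, it was 0.25, with 5 of 20 genes still higher and the list still past camera (adjusted p = 0.0277). With a granulocyte score in the fit it was 0.16, and with fry the list did not pass (adjusted p = 0.0835).

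Other lists of thymocyte stages and lineages did not change as a whole. None of 22 genes of the DN1 and DN2 progenitor list passed, over all genes or adjusted over the list alone (median 0.21, camera adjusted p = 0.557). Kit, a growth factor receptor of early progenitors, had a change of 0.89 (SE 0.27, adjusted p = 0.0747). None of 22 genes of the DN4 and DP transition list passed either way (median -0.21, adjusted p = 0.698), and Trat1, a T cell receptor adaptor, had a change of -1.14 (SE 0.32, adjusted p = 0.0558). Of 15 genes of the gamma-delta T cell list, 3 rose and none fell (4 and 1 when adjusted over the list alone): Gpr83 (2.73, SE 0.28), Cd163l1 (1.47, SE 0.28) and the chemokine receptor Ccr10 (1.05, SE 0.24). That list had a median of 0.19 (adjusted p = 0.134) and passed without wild type replicate 2 (adjusted p = 0.0385). Among 19 E protein, Id protein and lineage factor genes, Runx1 alone passed (2 lower when adjusted over the list alone, median 0.17, adjusted p = 0.512), and Lef1 had a change of -0.83 (SE 0.23, adjusted p = 0.0561).

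Genes of ribosome production fell together in the arrays labelled double knockout. Of 26 tested, 14 were lower and none higher (21 lower when adjusted over the list alone), with a median log2 change of -1.01. Gnl3, nucleostemin, fell by 1.77 (SE 0.23, adjusted p = 0.00125), the small nucleolar RNA proteins Nop56 by 1.54 (SE 0.23) and Dkc1 by 1.37 (SE 0.21), and the processing factor Rrp9 by 2.00 (SE 0.32). This was the 1 list of 28 tested that passed both with the preset correlation (camera adjusted p = 8.01e-15) and with an estimated one (adjusted p = 0.0346).

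Genes of DNA replication fell as well, with 13 of 39 lower and none higher (22 lower when adjusted over the list alone). Dut, the dUTP pyrophosphatase, fell by 1.20 (SE 0.21), the cell cycle transcription factor E2f2 by 1.27 (SE 0.24), the replicative helicase subunit Mcm3 by 1.03 (SE 0.21) and the uracil glycosylase Ung by 1.39 (SE 0.29). The list's median was -0.75 (camera adjusted p = 2.48e-13, but adjusted p = 0.106 with an estimated correlation). None of 39 genes of the G2 and mitosis list passed, over all genes or adjusted over the list alone (median -0.05, adjusted p = 0.853). The mean log2 value of the mitosis genes was 9.37 on both wild type replicates 1 and 2, 8.30 on wild type replicate 3 and between 8.92 and 9.02 on the arrays labelled double knockout. Without wild type replicate 3 the mitosis list fell (median -0.38, 9 of 39 lower and 1 higher, adjusted p = 0.000875) and 27 of the replication genes were lower. Cell cycle inhibitors went both ways: Ccng2 (1.21, SE 0.21), Cdkn2d (1.55, SE 0.26) and Tob1 (1.19, SE 0.23) rose, and Cdkn1a, the p21 inhibitor, fell by 1.04 (SE 0.27), so that 3 of 16 were higher and 1 lower (4 and 1 when adjusted over the list alone, median 0.14, adjusted p = 0.116).

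Lists of metabolic and chaperone genes were lower in the arrays labelled double knockout. Of 18 genes of cholesterol synthesis, 4 fell and 1 rose (9 and 1 when adjusted over the list alone, median -0.67, camera adjusted p = 1.2e-05, but adjusted p = 0.106 with an estimated correlation). The isomerase Idi1 fell by 1.96 (SE 0.24), the epoxidase Sqle by 1.87 (SE 0.25), Fdft1 by 1.20 (SE 0.24) and Lss by 1.24 (SE 0.26). Stard4, a cholesterol transporter and not an enzyme of the pathway, was the member that rose (0.98, SE 0.25), although another bright probe set gave 0.14 (SE 0.26). Of 16 genes of glycolysis, 3 fell and none rose (6 and 1 when adjusted over the list alone, median -0.44, camera adjusted p = 0.000944, but adjusted p = 0.106 with an estimated correlation): the enzymes Tpi1 (-1.17, SE 0.20) and Pkm (-1.60, SE 0.38) and the lactate transporter Slc16a1 (-1.27, SE 0.27). Of 15 heat shock genes, Hsph1 (-2.11, SE 0.34) and Hsp90aa1 (-1.50, SE 0.26) fell and none rose (4 and 1 when adjusted over the list alone). The heat shock list passed (median -0.50, camera adjusted p = 0.0104, but adjusted p = 0.307 with an estimated correlation), except without double knockout replicate 3 (adjusted p = 0.0565) and with fry (adjusted p = 0.0835).

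Glucocorticoid response genes rose in the arrays labelled double knockout, with 14 of 23 higher and 2 lower (15 and 3 when adjusted over the list alone). Txnip, the thioredoxin inhibitor, rose by 2.54 (SE 0.21, adjusted p = 9.83e-05), from 1276 ± 292 to 7490 ± 662 (mean intensity and SD, n = 3 each). The kinase gene Sgk1 rose by 1.95 (SE 0.26) and Bcl2l11, which encodes the death promoter Bim, by 2.12 (SE 0.26), again beside Il7r. The leucine zipper gene Tsc22d3 rose by 3.13 (SE 0.64) on its brightest probe set, while another bright probe set gave 2.23 (SE 0.26) and a further 1 gave -0.38 (SE 0.38). Against the direction of the list, Cdkn1a and Il2ra fell. The list's median was 1.39 (camera adjusted p = 7.07e-09, but adjusted p = 0.106 with an estimated correlation). Immediate early genes, which are switched on within minutes of a stimulus, rose as well, with 10 of 28 higher and 1 lower (15 and 1 when adjusted over the list alone). The transcription factor genes Fosl2 (3.13, SE 0.30), Klf4 (2.07, SE 0.28) and Fos (1.99, SE 0.31) rose while Myc fell, and the median was 0.87 (camera adjusted p = 3.82e-10, but adjusted p = 0.106 with an estimated correlation).

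Genes reported elsewhere as EGR targets had 4 of 20 members higher and 1 lower in the arrays labelled double knockout (5 and 1 when adjusted over the list alone). The diacylglycerol kinase Dgka rose by 1.27 (SE 0.22), the death inhibitor Bcl2 by 1.18 (SE 0.24, with 1.95, SE 0.41, and 0.03, SE 0.25, on other probe sets), the cytokine Tnf by 1.11 (SE 0.27) and the death ligand Fasl by 1.08 (SE 0.28), while Cdkn1a fell. The median was 0.37 (camera adjusted p = 0.0275, but adjusted p = 0.453 with an estimated correlation). The call was lost without wild type replicate 3 (median 0.13, adjusted p = 0.131), without double knockout replicate 3 (0.0565), without the intensity filter (0.0636), with array weights (0.134) and with fry (0.107). With a granulocyte score in the fit, an alternative chosen after seeing the data, the median was 0.05 (adjusted p = 0.231).

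Genes that promote cell death rose as a list, with 5 of 22 higher and 1 lower (6 and 1 when adjusted over the list alone). Bmf rose by 2.26 (SE 0.23, adjusted p = 0.000306), Bcl2l11 as above and Bik by 1.38 (SE 0.26), all 3 of the BH3-only class, and cytochrome c, Cycs, fell by 1.06 (SE 0.17). The median was 0.28 (camera adjusted p = 0.0128, but adjusted p = 0.307 with an estimated correlation). That call was lost without wild type replicate 3 (adjusted p = 0.0747), without the probe sets marked as reading several sequences (0.0572) and with the mean of all probe sets of a gene (0.055). Of 13 genes that oppose cell death, Birc3 (1.60, SE 0.24) and Bcl2 rose and the kinase gene Pim3 fell by 0.89 (SE 0.23), with 4 higher and 1 lower when adjusted over the list alone, and the list did not pass (median 0.40, adjusted p = 0.0996), except with fry (adjusted p = 0.0211). Of 21 p53 target genes, Ercc5 (1.18, SE 0.23) and Perp (1.20, SE 0.30) rose and Cdkn1a fell, with 5 higher and 4 lower when adjusted over the list alone (median 0.23, adjusted p = 0.417). Of 26 interferon response genes, Usp18 alone passed (1.14, SE 0.27), also when adjusted over the list alone (median 0.08, adjusted p = 0.38).

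**Figure D3:**
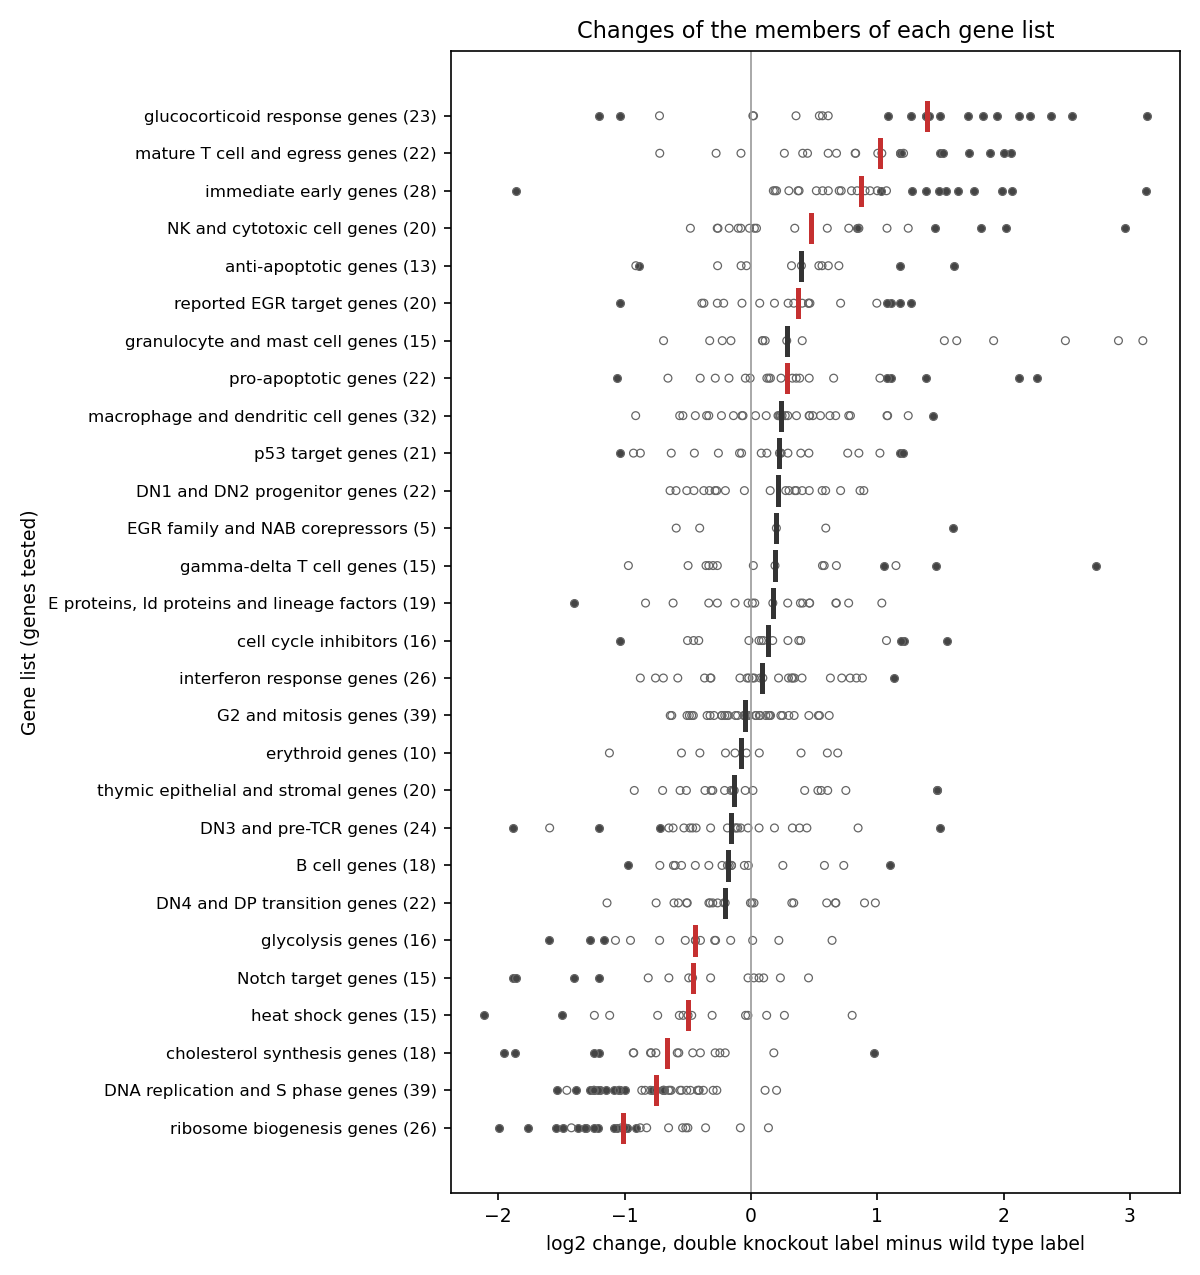
Log2 change of each tested member of 28 gene lists, for the arrays labelled double knockout minus those labelled wild type, with filled points for genes at an adjusted p below 0.05 and bars at the medians, red where camera with its preset correlation passed. Medians run from -1.01 for ribosome biogenesis genes to 1.39 for glucocorticoid response genes, and ribosome biogenesis was the list that also passed with an estimated correlation.

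Transcripts of other cell types were measured in the same arrays. Granulocyte genes were nearly missing from wild type replicate 3 and strong on the other 5 arrays: S100a8, a calcium-binding protein of neutrophils, read 20.4 there against 5282 and 9927 on the other wild type arrays and a mean of 10820 on the arrays labelled double knockout. None of 15 granulocyte and mast cell genes passed, over all genes or adjusted over the list alone (median 0.28, mean 0.88, camera adjusted p = 0.262). The list passed without wild type replicate 2 (adjusted p = 0.0143). In the B cell list, Cd79b rose by 1.10 (SE 0.27) and Ighm fell by 0.97 (SE 0.25) among 18 genes, also when adjusted over the list alone (median -0.18, adjusted p = 0.404). Of 32 macrophage and dendritic cell genes, Cd14 rose by 1.44 (SE 0.35), none passed when adjusted over the list alone, and the list did not pass (median 0.24, adjusted p = 0.116) except without wild type replicate 2 (adjusted p = 0.00321). None of 10 erythroid genes passed either way, and the list's median of -0.08 and mean of -0.07 lay below 0 while camera's direction was upward (adjusted p = 0.88). With a granulocyte score in the fit, an alternative chosen after seeing the data, the erythroid list passed (median 0.51, 2 genes higher, adjusted p = 0.0256), as did the B cell list (median -0.58, adjusted p = 0.0191). Of 20 thymic epithelial and stromal genes, the receptor gene Pdgfrb rose by 1.47 (SE 0.26), also when adjusted over the list alone. That list had a median of -0.14 and a mean of 0.07, with camera upward (adjusted p = 0.844), and it passed with the filter at the 60th percentile (adjusted p = 0.0303). None of the 4 sex-linked genes tested passed either way, and this list was too short for a list test.

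Fisher's exact test detected no excess of changed genes around the targeted genes. Their share was higher around both, and the wide intervals leave an excess possible. Of 75 genes tested among the 100 annotated genes on each side of Egr1, 8 changed (10.7%), against 6.95% of the genes elsewhere (odds ratio 1.6, 95% confidence interval 0.661 to 3.35, two-sided exact p = 0.248, adjusted p = 0.433). They included Epb41l4a, and Hspa9, a mitochondrial chaperone that fell by 1.14 (SE 0.21) and was named here after its value was seen. Around Egr3, 5 of 55 genes changed (9.09%, against 6.96% elsewhere, odds ratio 1.34, interval 0.415 to 3.34, exact p = 0.433). Probe sets of a gene did not always move together: 230 of the changed genes had another probe set with a mean intensity of at least 100, which in 169 moved the same way at an unadjusted p of at most 0.05. In 29 of them (12.6%), another bright probe set moved by less than 0.25 times as much and did not reach that p. In 2, named here after their values were seen, another bright probe set moved the opposite way at that p: Gfer (1.10, against -1.85, SE 0.24) and Bbip1 (1.31, against -0.78, SE 0.28).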

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

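The fit with a granulocyte score as a covariate was chosen after the results were seen, the other alternatives before. Counts of changed probe sets and genes stayed within 1.5 times of the reported count with values as deposited, quantile normalization, both offsets, both filters and no intensity trend, and the median change of all genes lay between -0.024 and 0.0048 under the scalings. With values as deposited 990 genes changed, 916 of them among the 920, and with quantile normalization 1017, 903 of them shared. Array weights gave 3417 changed probe sets (1769 higher, 1648 lower) and 2909 genes, and the granulocyte score 2539 probe sets (1225 higher, 1314 lower) and 1728 genes. The causes were not tested. When 1 array was left out, changed probe sets ranged from 376 to 2744, higher ones from 243 to 1381 and lower ones from 133 to 1363. Changed genes ranged from 279 without double knockout replicate 1 to 1903 without wild type replicate 3, and of the 1903 genes 905 were among the 920. The Egr1 change ranged from 1.49 to 1.76 with adjusted p from 0.00381 to 0.0613 when 1 array was left out, and it lost its call without double knockout replicate 1. Over all alternatives its adjusted p ranged from 0.00126 to 0.0613. The Egr3 change lay between -1.03 with the granulocyte score and -0.36 with offset 64, and between -0.98 and -0.39 when 1 array was left out, and passed in none of these fits. The replicate numbers do not pair the samples: same-numbered arrays had correlations of -0.047, -0.13 and -0.29 in their deviations from the group means. As a block, they left 573 probe sets (394 higher, 179 lower) and 369 genes, all of them among the 920, in a fit with fewer degrees of freedom. With an estimated correlation 1 list passed in place of 12. The other settings gave between 10 and 15 lists. The odds ratio around Egr1 was 2.11 and 1.19 with windows of 50 and 200 genes, and around Egr3 1.34 and 1.55, none past the threshold. Of the 24 named genes, 22 kept their direction under every alternative that gave a value. Cep85 was lowest with offset 1 (-3.49). When 1 array was left out it lay between -3.4 without wild type replicate 2 and 0.03906 without wild type replicate 3, lost its call at -0.27 without wild type replicate 1, and Gja1 turned to 0.44 without the probe sets marked as reading several sequences, because another probe set then stood for each gene. Among lists that did not pass, camera's direction turned for erythroid genes with offset 64 (median -0.17), the replicate block (-0.0809) and without wild type replicate 2 (-0.48), for G2 and mitosis genes without wild type replicate 1 (0.18) or 2 (0.12), for B cell genes without wild type replicate 2 (0.0294), for granulocyte and mast cell genes with array weights (0.19) and the granulocyte score (-0.19), and for macrophage and dendritic cell genes with that score (0.0146). Without wild type replicate 3 the medians were -0.384 for G2 and mitosis, -0.497 for B cell and 0.432 for erythroid genes. The causes were not tested. Dim signal limits Egr3, whose probe sets read between 12.5 and 92.2.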

Other observations

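The 3 gene groups in this paragraph and their genes were chosen after their values were seen, so their counts are descriptions and not tests. In the arrays labelled double knockout, 6 of 13 enzymes of folate, serine, glycine and polyamine metabolism fell and none rose, with a median log2 change of -1.07. Beside Srm, these were the serine hydroxymethyltransferases Shmt1 (-1.76, SE 0.23) and Shmt2 (-2.37, SE 0.51), Mthfd1 (-2.20, SE 0.41), Mtap (-1.99, SE 0.32) and Gcsh (-1.96, SE 0.23). Among 15 genes of T cell inhibition and costimulation, most of them receptors, with interleukin 10 and the secreted protein gene Fgl2 among the others, 6 rose and none fell, with a median of 1.21. Pdcd1, the PD-1 receptor, rose by 2.81 (SE 0.31), Il10 by 2.74 (SE 0.32), Fgl2 by 3.00 (SE 0.30), Tnfrsf18 by 2.02 (SE 0.36) and Cd160 by 1.26 (SE 0.30), beside Ctla4. Of 19 aminoacyl-tRNA synthetase genes, Wars (-1.08, SE 0.26) and Farsb (-0.88, SE 0.22, with 0.43, SE 0.25, on another bright probe set) fell and none rose, with a median of -0.58.

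The tests on Egr1, on the NK and B cell scores, on granulocyte RNA, on the members of the NK list and on dividing cells were chosen after the results were seen, and those on RNA quality and other splits before. The bound for the 2 score differences was made stricter, and a condition on the spread added for RNA quality, after their values were known; under the first bound the S phase difference would have argued against a lower share of dividing cells. Egr1 was higher in the arrays labelled double knockout by 1.60 on the log2 scale. An exchange of single arrays between the groups is argued against, since 0 of the 6 arrays correlated best with an array of the other group and the Egr1 signals of the groups do not overlap. The margin was small for wild type replicate 3, whose correlation was 0.95 with its best partner and at most 0.942 with the other group. An exchange of all 6 labels could not be excluded, because the brighter Egr3 probe set changed by -0.59 (SE 0.35), within its spread, on signals of at most 92.2. Without wild type replicate 3 it changed by -0.98 (SE 0.285) and with the granulocyte score by -1.03 (SE 0.316), a direction that the labels as given would have, but the place of the probe set in the gene is not given in the sources used here. Transcript of the disrupted gene that still carries the probe set's sequence may also give the signal, and with 1 Egr1 probe set on the array these cannot be told apart. The loss of Egr1 and Egr3 themselves, as a biological cause of a higher remaining transcript, was not tested. Immediate early genes also rose in the arrays labelled double knockout, with 10 of 28 higher, 1 lower and a median of 0.87. Whether the Egr1 rise belongs with theirs was not tested either.

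The rise of 14 genes of the mature T cell and the NK and cytotoxic lists had a median of 1.62 in the arrays labelled double knockout. A lower share of the main cell type would raise markers of other types alike only if those types kept their proportions. The NK score minus the B cell score differed by 0.775 between the groups (SE 0.0573, n = 3 and 3). The NK list was singled out because it rose, and 4 of the 18 tested B cell genes are also in other lists. No conclusion on the share of the main cell type is drawn from this difference. The near absence of granulocyte RNA from wild type replicate 3 is argued against as the whole cause for the mature T cell list, whose mean change over all members was 0.931 (SE 0.117) and 0.865 (SE 0.159) without that array. For the NK and cytotoxic list it stays open, with a mean of 0.635 (SE 0.235) and 0.451 (SE 0.193) without that array; a first test, on the 14 genes alone, was set aside because they were picked for their change. NK cells or cytotoxic T cells among the sorted cells may still add to it: 13 of 20 tested genes of that list lay above 0, while its gene of highest signal, Gzma, was at 12510 ± 2900 in the wild type arrays and 11830 ± 1270 in the others (mean intensity and SD, n = 3 each), and 3 of the 20 are in other lists. Whether the sort removed such cells is not given in the sources used here, so this cannot be told apart from a change in the thymocytes, as the genotype labels would have it.

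The fall of ribosome biogenesis and S phase genes was weighed in the same way. For RNA quality, the log2 ratio of 3' to 5' signal differed between the groups by less than its SE, for actin (-0.187, SE 0.249) and Gapdh (-0.228, SE 0.396). The mean change of the ribosome biogenesis genes was -0.996 (SE 0.0517), and -1.02 (SE 0.0537) with the actin ratio in the fit (S phase genes -0.79, SE 0.188, and -0.687, SE 0.157). A ratio so alike in both groups could hardly take up such a change, so no conclusion is drawn from that fit. The ratios themselves show no difference in RNA quality between the groups beyond their spread. A lower share of dividing cells may contribute to the fall of S phase genes. It would lower mitosis genes alike, and the S phase score minus the mitosis score differed by -0.749 (SE 0.194, n = 3 and 3), or -0.566 without wild type replicate 3, which does not settle it with so few arrays of unequal spread. The genotype as a cause was not tested apart from these.

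The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most probe sets changed by limma (1358, and 0 in the highest other) and genes (920, and 0 in the highest other). For gene lists at the preset correlation, 3 of the 10 splits gave at least as many as the real 12, and the highest other gave 14.

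Signals of sex-linked genes went together in unusual ways. Eif2s3y, a gene of the Y chromosome, read 476, 13.2 and 0.625 on wild type replicates 1, 2 and 3 and 217 ± 42.4 on the arrays labelled double knockout (SD, n = 3), while Xist, the transcript of the inactive X chromosome, read 1439, 3977 and 5311 on the wild type arrays and 4908 ± 1060 on the others. The Y chromosome genes Kdm5d and Uty read 144 and 63.7 on wild type replicate 1 with their brightest probe sets, and 10.3 to 29.5 and 11.4 to 23.4, about the level of the brightest bacterial controls, on the arrays labelled double knockout. A single male or female mouse would not be expected to give both Xist and Y chromosome transcripts, as wild type replicate 1 does, and whether RNA of several animals was combined there is not given in the sources used here. On the arrays labelled double knockout the Y chromosome signal rests on Eif2s3y alone (199.5, 265.1 and 185.7), beside Xist between 3910 and 6015. It settles nothing, but RNA of several animals is left open there as well. Wild type replicates 2 and 3 lacked the Eif2s3y signal, so such a mix, if present, would not be even between the groups.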
